A study of Mus musculus with 9 samples.

How the data were processed

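RNA was measured by sequencing in 9 libraries of mouse testis, 3 in each of 3 groups. All mice had received busulfan, an alkylating drug that depletes germ cells. The groups differed in what was injected afterwards: PBS (BP, replicates 5, 6 and 7), exosomes from the blood of wild-type mice (BE, replicates 6, 7 and 8), or exosomes from mice with a disturbed gut microbiota (BdE, replicates 5, 6 and 7). Exosomes are small vesicles that cells release into body fluids. The labels do not say whether each replicate was a separate animal, so the p-values measure the spread between these samples. No label says that the numbers of the replicates pair the libraries, and no pairing was assumed. The correlations of the residuals of libraries with the same number lay between -0.0973 and 0.21, and BE 8 has no partner. Those with different numbers lay between -0.175 and 0.18. With 3 libraries per group these values cannot exclude a pairing.

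The deposited table gives a read count and an FPKM value for 55401 genes in each library. Per the file headers, the counts are numbers of reads per gene, and all are whole numbers. The FPKM values were made by the authors as fragments per kilobase of gene scaled to the library total, with 0.0001 in place of 0. In the deposited values FPKM was proportional to the count within a library (SD of the log2 ratio 0.00043 over 7747 genes with at least 1000 reads). The labels name Bowtie 0.12.2 and the mouse build mm8 without their roles. The coordinates in the table are those of GRCm38: 51957 genes (93.8%) have the same start and end in GENCODE release M21. The counting program and the strand setting are not given in the sources used here. The extraction text of the labels names retinas although the tissue is given as testis, so a list of photoreceptor genes was included as a check. Annotation terms withheld from 2304 genes are not reported here.

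Library totals lay between 57923652 and 70103125 counts. At these depths 3 counts, the upper limit that a count of 0 allows, equal 0.0428 to 0.0518 CPM, the count scaled to a common library total. Shares of counts in a single library are given with a Wilson interval at 95%. Intervals and floors cover counting error only.

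The choices below were made before the data were examined unless the text says otherwise. Genes with an FPKM of at least 1 in at least 3 of the 9 libraries were tested (14570 genes, which held 98.6% or more of each library's counts). The plan named limma on log2(FPKM+1) for data without counts and a count model for data with them. Because counts are present, the test was edgeR 4.0.16 quasi-likelihood (R 4.3.3) with TMM normalization, a term for the group and all 9 libraries in 1 model. Each of the 3 pairs of groups was compared by a two-sided test, and the 3 groups were also compared together by an F test. P-values were adjusted by Benjamini-Hochberg over all genes tested, and an adjusted p under 0.05 was the threshold for a change. The biological coefficient of variation was 0.288 and the prior degrees of freedom were 2.47. CPM values are TMM-scaled and are given as mean ± SD over 3 libraries. Log2 fold changes are given with the standard error (SE) of the fit.

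The 33 gene lists were fixed from general knowledge of testis cell types and pathways. For 29 of them at least 5 members were tested, and these were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. For a list, the median log2 fold change of its members is given, with the number of members past the threshold adjusted over all genes tested and adjusted over the list alone. The level of a list in a library is the mean of log2(FPKM+1) over its members, and levels were compared among the 3 groups by an exact permutation test of the F statistic over 1680 assignments (280 distinct splits), whose smallest possible p is 0.00357. List medians, means and tests differed in sign for 5, 5 and 4 of the 29 lists in the 3 comparisons and for 0 of the lists past the threshold.

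Genes are named by a rule. For each pair of groups it takes the 10 largest rises and the 10 largest falls among genes past the threshold whose libraries do not overlap between the groups, leaving out predicted genes and antigen receptor segments. Where fewer than 10 genes pass, it adds the 10 smallest p-values, which are said not to pass. From each list it takes up to 4 members past the threshold and, where fewer than 2 pass, the 2 members with the highest mean FPKM. Ddx4, Sycp3, Prm1, Sox9, Cyp11a1 and Kit were fixed as reference genes. The rule was also applied to the comparison of the 6 BP and BdE libraries alone and to the fit without BE 6. Both fits were planned as alternatives, but naming genes from them was not in the plan. The fit without BE 6 was singled out because BE 6 lay with the BP libraries. The p-values of that fit do not allow for that choice. Genes named outside the rule were chosen after their values were seen. Among them are Crx, Crisp1, Adam7 and Rnase9, which were not tested.

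Alternative settings chosen in advance were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, median-ratio size factors, TPM, quantile normalization, only the 6 libraries compared, limma without its trend and with trend and robust, array weights, a term for the replicate number, the level of the meiotic prophase list as a covariate, DESeq2 1.42.0, DESeq2 size factors in edgeR, other thresholds, and each library left out in turn. Alternatives chosen after seeing the data were limma on log2(FPKM+1), edgeR with robust spread, a fit without the mitochondrially encoded genes, a correction for transcript length and GC content, a fit without BE 6 and BP 5, the 6 libraries compared with each left out in turn, and KEGG pathways (296 with 10 to 300 tested genes, taken from the deposited annotation). Length and GC content were known for 14553 of the tested genes (99.9%). Rescaling FPKM to TPM moved the median of all genes by -0.243 (BE minus BP) and -0.272 (BdE minus BP) on the log2 scale, and values under TPM are relative to those shifts.

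The test was tried on simulated data with the spread of these libraries and 50 changed genes per fold. Each gene was drawn on its own, so a shift of a whole library, such as that of BE 6, was not simulated. It recovered 38% of 2-fold and 92% of 4-fold changes in BE minus BP, 50% and 92% in BdE minus BP, and 38% and 90% in BdE minus BE, with 6, 7 and 2 false calls among the unchanged genes. A 2-fold fall set into the cholesterol list was called, as was 1 of the 28 lists left unchanged. Tables were read with Python 3.11.15, pandas 2.3.3 and data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9.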

Results

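Gene expression was measured in testis from mice whose germ cells had been depleted with busulfan. There were 3 libraries in each of 3 groups. The groups had received PBS (BP), exosomes from the blood of wild-type mice (BE), or exosomes from mice with a disturbed gut microbiota (BdE). The BP libraries (replicates 5, 6 and 7) held 57923652, 70103125 and 69365610 counts. The BE libraries (replicates 6, 7 and 8) held 68489233, 69343187 and 68311053 counts, and the BdE libraries (replicates 5, 6 and 7) 69609697, 67244116 and 66878877. The share of counts from the mitochondrial genome, which codes for subunits of the respiratory chain, was 7.52% ± 0.46 in BP, 11.98% ± 4.15 in BE and 12.5% ± 0.83 in BdE (SD, n = 3). In BE the library of replicate 6 held 7.19% (Wilson interval at 95%, 7.188 to 7.2%), within the range of BP, against 14.52% (14.514 to 14.53%) and 14.24% in BE 7 and BE 8. Across genes, BE 6 correlated with the BP libraries at a mean r of 0.973 and with BE 7 and BE 8 at 0.938, while the BP libraries correlated with one another at 0.972 (across genes, which are not independent replicates).

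**Figure D1:**
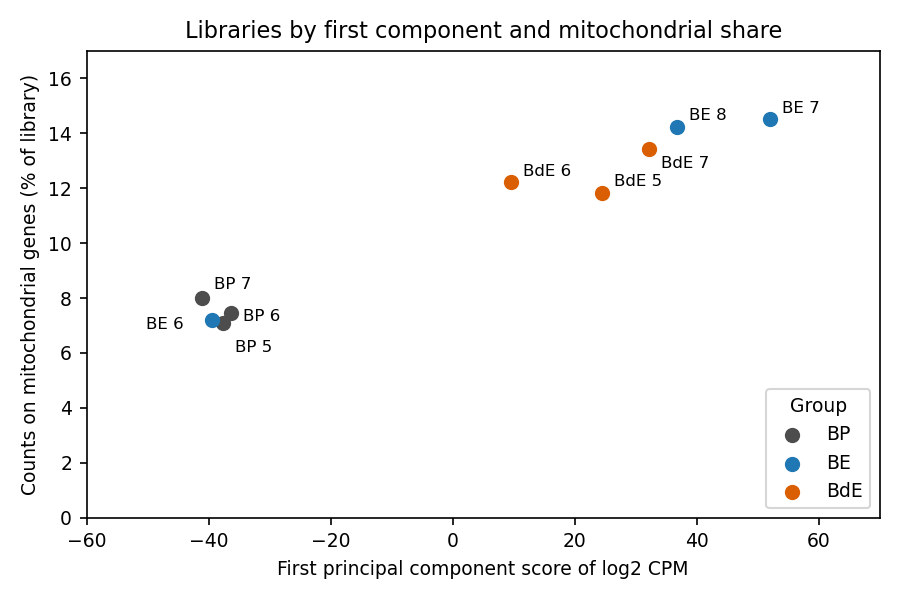
Score of each library on the first principal component of the tested genes (36.5% of the variance) against its percent of counts from the mitochondrial genome; each point is 1 library, named by group and replicate. The BP libraries and BE 6 lie between -41.1 and -36.4 with 7.1 to 8.01% mitochondrial counts, and the other BE and the BdE libraries lie between 9.54 and 52 with 11.84 to 14.52%.

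The comparison of BE with BP asked what blood exosomes from wild-type mice changed in the depleted testis. Ccdc71, which codes for a coiled-coil protein, rose by 1.76 on the log2 scale (SE 0.138, edgeR adjusted p = 0.0118). It went from 19.4 ± 3.48 CPM in BP to 65.8 ± 0.0343 in BE (SD, n = 3), higher in 3 of 3 BE libraries than in every BP library. Abl1, a tyrosine kinase gene with roles in the cytoskeleton and in DNA damage signalling, rose by 1.44 (SE 0.139, edgeR adjusted p = 0.0312), from 54.0 ± 7.75 to 146 ± 22 CPM. Genes of cholesterol synthesis, which supplies the precursor of testosterone, lay lower in BE as a group (median log2 fold change -0.59, 18 of 18 members negative, camera adjusted p = 2.39e-06). The 9 mitochondrially encoded genes lay higher (median 0.72, 9 of 9 positive, adjusted p = 1.79e-06). Both list calls were lost with the correlation estimated from the data (adjusted p = 0.834 with an estimated correlation). A trend on gene length ran with these changes: the rank correlation of transcript length with expression relative to the mean of the libraries was 0.21 to 0.286 in BP and 0.258 in BE 6, against -0.209 in BE 7 and -0.226 in BE 8. With 1 library left out the cholesterol median ran from -1.32 (without BE 6) to -0.359 (without BE 7), and the mitochondrial median from 0.545 (without BE 8) to 0.998 (without BE 6). With quantile normalization the mitochondrial median was 0.0966 and did not pass (adjusted p = 0.203; 1.12e-12 to 0.834 over the alternatives).

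Ccdc71 (ENSMUSG00000049305, GRCm38 chromosome 9, 108460527 to 108465938) and Abl1 (ENSMUSG00000026842, chromosome 2, 31688376 to 31800339) were the 2 genes past the threshold among 14570 tested. Ccdc71 overlaps Klhdc8b on the other strand and Abl1 overlaps Gm13427, and the strand of counting is not given in the sources used here. Klhdc8b had 6399 to 6743 counts in BP, 6787 in BE 6 and 8678 to 10689 in BE 7, BE 8 and BdE, against 1091 to 4903 for Ccdc71. Whether its reads entered the counts of Ccdc71 was not tested. Gm13427 had at most 43 counts in any library. In Ccdc71 and Abl1 BE 6 lay with the other BE libraries: Ccdc71 reached 65.8 CPM in each BE library, and Abl1 reached 171 CPM in BE 6. Both passed with BE 6 in the model, which favours genes in which BE 6 lies with BE 7 and BE 8. At an unadjusted p under 0.05 there were 1865 genes (12.8%; 1134 higher, 731 lower), against 728 expected by chance. The genes with the next smallest p did not pass by edgeR. They were Gstp2, a glutathione transferase gene (1.13, adjusted p = 0.23), and Tekt2, a gene of the flagellar axoneme (1.55, adjusted p = 0.301). Next came Il6st, which codes for the shared receptor of the interleukin 6 family (-0.70, adjusted p = 0.307), and Fcgrt, the neonatal Fc receptor gene (-0.77, adjusted p = 0.358). Over the alternatives the adjusted p of Ccdc71 ranged from 2.1e-26 to 0.7 (past the threshold in 23 of 29) and that of Abl1 from 9.2e-16 to 0.7 (13 of 29). Ccdc71 did not pass without BP 6 (adjusted p = 0.0813), BE 8 (0.0866) or BdE 7 (0.0613). Abl1 did not pass without BP 6 (0.228), BP 7 (0.112), BE 7 (0.0807), BE 8 (0.0866), BdE 5 (0.0763), BdE 6 (0.102) or BdE 7 (0.109). DESeq2 called 61 genes.

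The count of genes rested on which libraries entered the model. Without BE 6 it was 4351, and without BP 5 it was 6. It was 0 without BP 6, without BE 8 or without BdE 7, and 1 without BdE 5 or without BdE 6. Without BE 6, Kctd12, which codes for a subunit of GABA(B) receptors, was lower, with 0 counts in BE 7 and BE 8 against 5241 to 9626 in the other 7 libraries (6911 in BE 6). Ablim1, an actin-binding LIM protein gene, lay 3.54 lower (SE 0.267, edgeR), from 56.1 ± 8.56 CPM in BP to 4.25 and 5.41 in BE 7 and BE 8. Idi1, an enzyme gene of cholesterol synthesis, changed by -2.05 (SE 0.231). Adgre1 and Csf1r, macrophage receptor genes, changed by -2.16 (SE 0.192) and -1.52 (SE 0.166). Des, which codes for the muscle filament protein desmin, changed by -1.35 (SE 0.114), and Col3a1, a fibrillar collagen gene, by -1.20 (SE 0.0837). Spp1, the osteopontin gene, lay 2.64 higher (SE 0.733), which rested on BE 8 (132 CPM, against 14.1 in BE 7). Each of these genes passed in that fit, which is itself counted among the alternatives. Over the alternatives each passed in 3 of 28 or 29 (Spp1 in 2), with an adjusted p from 0.00052 to 0.869 (0.00465 to 0.989 for Spp1). BE 6 is the BE library nearest to BP, so leaving it out favours more calls, and the p-values do not allow for that choice. The 0 counts of Kctd12 may not mean a lack of its transcript, since the counting program is not given. Mir5130, inside Kctd12 on the same strand, had 2 and 4 counts in BE 7 and BE 8. Other large falls of that fit were in gene families, such as Cd300ld3 with Cd300ld5 and Klk1b1 with Klk1b8.

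Of the 29 lists tested in BE minus BP, 8 passed with the preset correlation, 2 higher and 6 lower, and 0 passed with an estimated correlation (camera) or by fry (lowest adjusted p = 0.498). In the 2 BE libraries that differed most from BP, BE 7 and BE 8, the trend on gene length also had the opposite sign (-0.209 and -0.226). Peritubular myoid and smooth muscle genes, which mark the contractile cells around the tubules, had a median of -0.54 (adjusted p = 2.1e-06). Of the 11 members 7 were lower when adjusted over the list alone (0 over all genes tested), among them Tpm2 (-0.54, SE 0.134) and Actg2 (-0.71, SE 0.191). Macrophage genes had a median of -0.53 (adjusted p = 1.35e-05), stromal fibroblast genes -0.54 (adjusted p = 0.00474) and fatty acid metabolism genes -0.22 (adjusted p = 0.00249), each with 0 members past the threshold over all genes tested or adjusted over the list alone. Leydig cell and steroidogenesis genes had a median of -0.45 (adjusted p = 0.00516). Hsd3b1, an enzyme gene of testosterone synthesis, was lower adjusted over the list alone (-0.76, SE 0.181, adjusted p = 0.032). Of the cholesterol genes 1 member, Msmo1, was lower adjusted over the list alone, and of the mitochondrially encoded genes 8 of 9 were higher. Elongating spermatid genes had a median of 2.36 with 6 of 6 members positive (adjusted p = 0.00173) and 0 members past the threshold either way. Among them were Smcp and Odf1, structural genes of the sperm tail (2.56, SE 1.14, and 2.65, SE 1.12). For these 8 lists adjusted p = 0.834 with an estimated correlation. The elongating spermatid call was lost without BE 6 (median 2.61, adjusted p = 0.0899) and the Leydig call without BE 7 (median -0.15, adjusted p = 0.0731). The other medians were most negative without BE 6: -1.02 for macrophages, -1.01 for fibroblasts, -0.933 for Leydig cells, -0.691 for myoid cells and -0.47 for fatty acids. They were nearest to 0 at -0.354, -0.433 and -0.147 for macrophages, myoid cells and fatty acids (without BE 7) and at -0.277 for fibroblasts (without BE 8). Over their alternatives the adjusted p of the 8 lists reached from 1.12e-12 to 0.834.

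The comparison of BdE with BP asked what exosomes from mice with a disturbed gut microbiota changed. Against PBS, genes of steroid production, lipid synthesis and the cells around the tubules lay lower in BdE as lists with the preset correlation. With an estimated correlation 0 of the 8 lists given here passed (adjusted p = 0.776 for each), and fry called 0 lists (lowest adjusted p = 0.411). The 2 groups also differed in the trend on gene length (rank correlation 0.21 to 0.286 in BP and -0.26 to -0.0907 in BdE). Cholesterol synthesis genes had a median of -0.71 (18 of 18 members negative, camera adjusted p = 1.45e-05; -1.08 without BdE 6 and -0.581 without BdE 7), and fatty acid metabolism genes -0.42 (14 of 16, adjusted p = 3.84e-05). Macrophage genes had a median of -0.48 (13 of 13, adjusted p = 0.000138) and stromal fibroblast genes -0.59 (9 of 9, adjusted p = 0.00643). Peritubular myoid genes had -0.44 (9 of 11, adjusted p = 0.00643) and Leydig cell genes -0.65 (9 of 12, adjusted p = 0.0158). The mitochondrially encoded genes lay higher (median 0.78, 9 of 9, adjusted p = 6.77e-06), as did interferon-stimulated genes (median 0.37, 11 of 14, adjusted p = 0.0411). The interferon median was 0.109 without BdE 6 and did not pass there.

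Over all genes tested with all 9 libraries, 1 gene passed in BdE minus BP: Ccdc71 (1.79, SE 0.138, edgeR adjusted p = 0.0105; 67.1 ± 5.70 CPM in BdE, SD, n = 3). At an unadjusted p under 0.05 there were 3509 genes (1738 higher, 1771 lower) against 728 expected by chance, and DESeq2 called 389. The next genes did not pass by edgeR. They were Prrc2b, which codes for a protein of RNA granules (-1.47, adjusted p = 0.0559), and Abl1 (1.26, adjusted p = 0.0559), then Chml, a Rab escort protein gene (-5.12, adjusted p = 0.0703), and Kdm2a, a histone demethylase gene (-0.52, adjusted p = 0.19). The count was 3257 without BE 6, 6 without BP 5, 5 without BdE 5, 4 without BE 8, 3 without BE 7 or BdE 6, 2 without BP 7 or BdE 7, and 0 without BP 6. Over the alternatives the adjusted p of Ccdc71 ranged from 2.99e-27 to 0.172 (past the threshold in 26 of 29), and it did not pass without BP 6 (0.073). In the 9-library model 8 of 9 mitochondrially encoded genes, 2 interferon-stimulated genes and 1 fatty acid gene passed adjusted over the list alone, and 0 members of any of the 8 lists passed over all genes tested.

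In the planned comparison of the 6 BP and BdE libraries alone, whose spread does not include that of the BE libraries, 3078 genes passed by edgeR, 1341 higher and 1737 lower. The largest falls with counts in every library were those of Chml (-5.12, SE 0.206, adjusted p = 0.00193), from 8.45 ± 0.627 to 0.241 ± 0.0381 CPM (SD, n = 3), and of Zfp260. The zinc finger gene Zfp260 fell by 4.12 (SE 0.533, adjusted p = 0.00867), from 25.3 ± 10.9 to 1.46 ± 0.683 CPM. Ablim1 fell by 3.40 (SE 0.221), to 5.31 ± 1.24 CPM, and Steap3, an iron reductase gene, by 2.64 (SE 0.218). Among the largest rises were Etohd2, a gene named for its response to ethanol (2.37, SE 0.491), Usp49, a deubiquitinase gene (1.89, SE 0.226), and Ccdc71 (1.79, SE 0.148). Slc39a9, a zinc transporter gene, rose by 1.72 (SE 0.175), from 16.9 ± 3.85 to 55.9 ± 1.33 CPM. Amn1, a gene of mitotic exit, rose by 1.60 (SE 0.118), from 10.1 ± 0.672 to 30.5 ± 3.32 CPM. With 1 library left out the count was 1257 without BP 5, 743 without BP 6, 1027 without BP 7, 2525 without BdE 5, 3140 without BdE 6 and 1033 without BdE 7. Of these, 1196, 716, 986, 2103, 2465 and 978 were among the 3078. The alternatives of the genes named here include the 6-library fit that named them. Over them the adjusted p of Chml ranged from 1.24e-16 to 0.279 (past the threshold in 7 of 28). Zfp260 (8.84e-05 to 0.404) and Ablim1 (6.7e-05 to 0.404) passed in 5 of 28. Steap3, Usp49, Slc39a9 and Amn1 also passed in 5 of 28 and Etohd2 in 2 of 27, each with an adjusted p of up to 0.404.

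The genes behind the list results in those 6 libraries belonged to several cell types. Among genes of Leydig cells, which make testosterone, the cholesterol carrier gene Star fell by 1.10 in testis RNA (SE 0.219, edgeR adjusted p = 0.021). Hsd3b1 fell by 0.56 (SE 0.0708) and the luteinizing hormone receptor gene Lhcgr by 0.87 (SE 0.157). In cholesterol synthesis, Sqle fell by 1.48 (SE 0.223), Idi1 by 1.28 (SE 0.192) and Cyp51 by 1.18 (SE 0.238). In fatty acid metabolism, the desaturase genes Scd1 and Fads2 fell by 1.31 (SE 0.149) and 0.99 (SE 0.0931). Among macrophage genes, Adgre1 fell by 1.84 (SE 0.17, adjusted p = 0.00534), Lyz2, a lysozyme gene, by 1.15 (SE 0.14) and Csf1r by 1.05 (SE 0.149). The collagen genes Col3a1 and Col1a2 fell by 0.93 (SE 0.0738, adjusted p = 0.00437) and 0.73 (SE 0.115), and the muscle genes Des and Lmod1 by 0.83 (SE 0.101) and 0.94 (SE 0.131). Of the mitochondrially encoded genes, mt-Nd1 rose by 0.90 (SE 0.126) and mt-Co3 by 0.78 (SE 0.113). The antiviral genes Ifit3 and Irf7, of a list that did not pass in those libraries, rose by 0.96 (SE 0.184) and 0.76 (SE 0.155). Each of these genes kept its direction in all alternatives run. Each passed in at most 5 of its 28 or 29 alternatives, the 6-library fit that named it among them. Their adjusted p reached up to 0.404 (0.459 for Lhcgr, 0.44 for Col1a2, 0.41 for Idi1 and 0.407 for Cyp51).

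**Figure D2:**
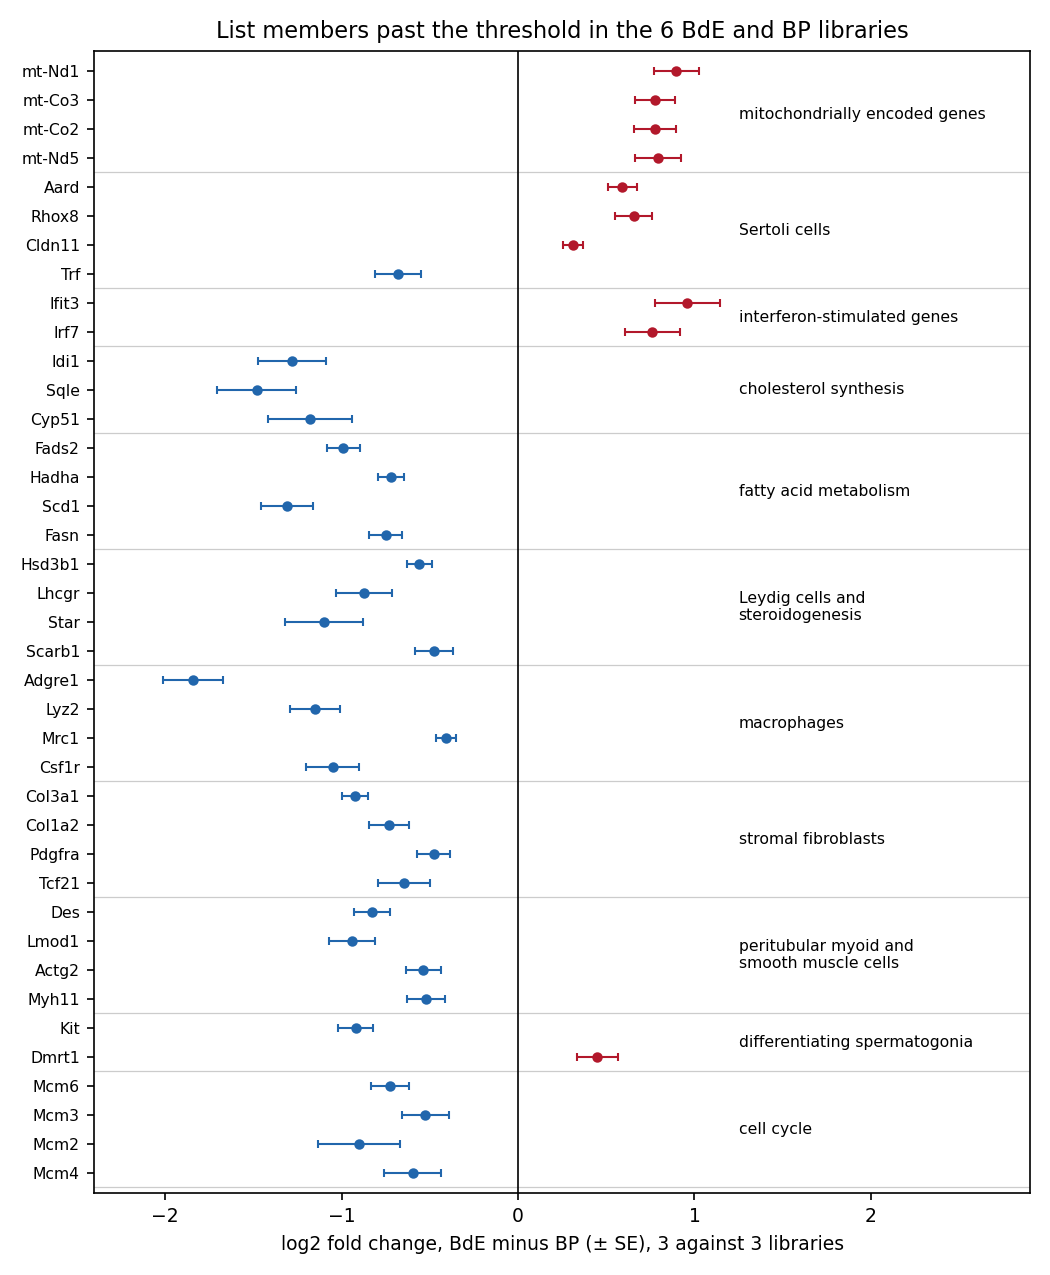
Log2 fold change (BdE minus BP) in the 6 libraries compared, for members of 11 lists past the threshold, up to 4 per list; points are estimates, bars are SE, red is higher and blue is lower in BdE, and members are grouped by list. The drawn members of the cholesterol, fatty acid, macrophage, fibroblast, myoid and Leydig lists lie below 0 and the mitochondrially encoded genes above it, with Adgre1 at -1.84 and mt-Nd1 at 0.90.

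As lists in the 6 libraries, 7 passed with the preset correlation and 0 with an estimated one (adjusted p of these lists 0.68 to 0.71). Of 18 cholesterol genes 10 were lower adjusted over the list alone and 7 over all genes tested (list adjusted p = 5.01e-07). In the same order the numbers were 13 and 10 of 16 fatty acid genes (8.47e-07), 10 and 8 of 13 macrophage genes (1.43e-06) and 5 and 5 of 9 fibroblast genes (0.000575). They were 7 and 4 of 11 myoid genes (0.00265) and 8 and 6 of 12 Leydig genes (0.00277). Insl3, a Leydig cell hormone gene and by FPKM (7910) the most abundant member of that list, was higher adjusted over the list alone (0.312, SE 0.0991) but not over all genes tested (adjusted p = 0.0707). Of the 9 mitochondrially encoded genes 9 were higher either way (7.08e-10). The 7 lists passed with each of the 6 libraries left out in turn. Interferon-stimulated genes did not pass there (median 0.37, adjusted p = 0.118). With all 9 libraries their call was lost without BP 6 (adjusted p = 0.0752), BE 6 (0.119), BE 7 (0.0629) or BdE 6 (median 0.11, adjusted p = 0.396). They passed in 15 of 31 alternatives (0.00384 to 0.776). The Leydig call of the 9-library model was lost without BdE 5 (median -0.57, adjusted p = 0.0868). Over their alternatives the adjusted p of the other lists reached from 1.03e-11 to 0.776, and each kept its direction in all of them. The mitochondrial median fell to 0.0257 with quantile normalization and did not pass there (adjusted p = 0.384).

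The comparison of BdE with BE asked whether the source of the exosomes mattered. Prrc2b (ENSMUSG00000039262, chromosome 2, 32151082 to 32234537) fell by 1.94 (SE 0.156, edgeR adjusted p = 0.0146). It went from 95.4 ± 8.57 CPM in BE to 24.9 ± 4.43 in BdE (SD, n = 3), with 69.0 ± 8.56 in BP, and every BdE library lay below every BE and BP library. Chml, which passed in BdE minus BP in the 6 libraries, lay at 6.98 ± 4.64 CPM in BE and 0.241 ± 0.0381 in BdE (-4.84, adjusted p = 0.136, not past the threshold). Rprd2, a regulator of RNA polymerase II (-2.17, adjusted p = 0.136), Kdm2a (-0.55, adjusted p = 0.165), and Lrrc57 (0.99, adjusted p = 0.238) did not pass either. Prrc2b was the 1 gene past the threshold, with 340 genes at an unadjusted p under 0.05 (176 higher, 164 lower; 728 expected by chance) and 26 genes by DESeq2. The count was 6 without BdE 5, 5 without BE 6, 4 without BdE 6, 3 without BE 7, 2 without BP 5, and 0 without BP 6 or BE 8. Prrc2b itself did not pass without BP 6 (adjusted p = 0.0719), BE 8 (0.0585) or BdE 7 (0.0618). Over its alternatives the adjusted p ranged from 4.11e-25 to 0.554 (past the threshold in 21 of 28).

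With all 9 libraries 0 lists passed between BdE and BE, and the number was 8 without BE 8 or BdE 6, 7 without BE 6, 6 without BdE 7 and 2 without BE 7 or BdE 5. The lowest adjusted p (camera) was 0.0509, for fatty acid metabolism (median -0.19; Fads2 -0.46, SE 0.368), and fry called 0 (lowest 0.98). Interferon-stimulated genes had a median of 0.16 (adjusted p = 0.0766), with Bst2 at 0.32 (SE 0.169). Without BE 6, lists of myoid (median 0.42), cholesterol (0.49), macrophage (0.32), fibroblast (0.36), Leydig (0.19) and interferon-stimulated genes (0.26) lay higher in BdE than in BE. The mitochondrially encoded genes lay lower (-0.24). Camera gave these 7 lists adjusted p from 7.71e-08 to 0.0335, and 0.521 to 0.857 with an estimated correlation. There 5 myoid, 2 Leydig and 2 fibroblast genes passed adjusted over the list alone, and 0 members of the 7 lists over all genes tested. Kctd12, at 0 counts in BE 7 and BE 8, was higher in BdE (5956 to 9626 counts), and those 0 counts may not mean a lack of its transcript. Gxylt1, a xylosyltransferase gene that modifies Notch receptors, lay 2.84 higher in that fit (SE 0.154), and Cdc42se1, a gene of a Cdc42 effector, 1.83 higher (SE 0.116). These 3 genes passed there, and over the alternatives, that fit included, they passed in 3 of 29, 3 of 28 and 4 of 29. Leaving out the BE library nearest to BP moves BE away from BP, and the p-values of that fit do not allow for that choice. A past-threshold result in BE or BdE against the shared BP libraries is not by itself a difference between BE and BdE; the values in this comparison are the test of that difference.

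The responses to BE and BdE ran in the same direction for many genes. Across the 14570 genes the log2 fold changes against BP correlated at r = 0.779, while sharing the BP libraries alone gave 0.50 (0.439 to 0.564 in 200 simulations). It was 0.596 without BE 7, 0.662 without BE 8 and 0.581 with no filter, and the simulation was not run for those fits. Genes were drawn independently in the simulation, so its range leaves out variation shared between genes. The sign was the same for 84.7% of the genes, against 66.7% in the simulations. Ccdc71 was the 1 gene past the threshold in both. The simulations gave 0 such genes, but they drew genes independently and were tested by limma instead of edgeR. With the real libraries, 25 of 100 splits into 3 groups gave at least 1 such gene. Without BE 6, 1299 genes were higher in both and 1570 lower in both, and 4 went opposite ways. Both comparisons use the same BP libraries, and the overlap that this sharing gives by itself was not simulated for that fit. Leaving out BE 6, the BE library nearest to BP, also favours shared calls. The count of shared genes, 1 with all libraries, was 2869 without BE 6, 5 without BP 5, and 0 without BP 6, BE 8 or BdE 7. Among the 3 groups tested together by edgeR, 2 genes differed (1937 at an unadjusted p under 0.05; 194 by DESeq2), with 3509 without BE 6, 6 without BdE 5, 5 without BP 5 and 0 without BP 6 or BdE 7.

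**Figure D3:**
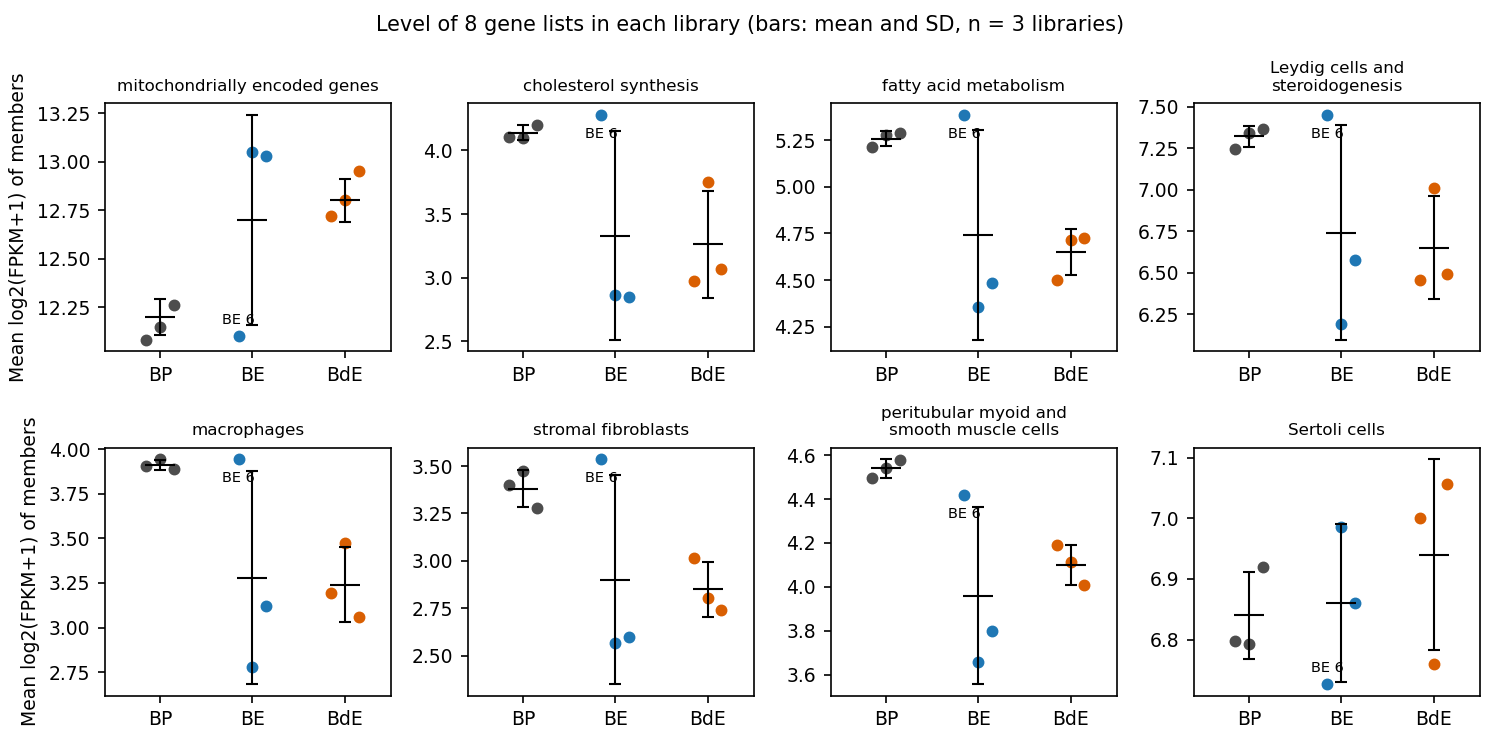
Mean log2(FPKM+1) of 8 gene lists in each library, with the mean (line) and SD (bar) of the 3 libraries of each group. In the myoid list BE 6 lies at 4.419, near the BP mean of 4.54, and BE 7 and BE 8 lie at 3.658 and 3.798.

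The level of a list in each library shows the spread within the groups. Myoid genes had a level of 4.54 ± 0.0428 in BP, 3.96 ± 0.405 in BE and 4.10 ± 0.0908 in BdE (SD, n = 3, exact permutation p = 0.0786). Fatty acid genes lay at 5.26 ± 0.0423, 4.74 ± 0.563 and 4.65 ± 0.125 (exact permutation p = 0.164). The lowest exact permutation p was that of the blood-testis barrier junction genes (5.07 ± 0.0343, 4.97 ± 0.0700 and 4.94 ± 0.0330, p = 0.0643, adjusted p = 0.594). Of the 29 lists 0 had an unadjusted p under 0.05, and 8 passed after adjustment without BE 6.

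Germ cell genes were tested because the model removes germ cells. Ddx4, an RNA helicase gene of the germ line, stood at 8.67 ± 5.53 CPM in BP, 12.4 ± 6.4 in BE and 9.47 ± 2.52 in BdE (SD, n = 3). Sycp3, a gene of the synaptonemal complex, stood at 3.27 ± 2.48, 5.86 ± 3.57 and 4.4 ± 1.5, and neither passed in any comparison (edgeR). Prm1, which packs sperm DNA, had 0 to 21 counts per library and was not tested. Kit, the receptor gene of differentiating spermatogonia that Leydig cells also express, stood at 136 ± 6.03 CPM in BP, 84.2 ± 51.7 in BE (143 in BE 6) and 71.8 ± 8.5 in BdE. It fell by 0.92 (SE 0.0994, adjusted p = 0.00668) in the 6 BP and BdE libraries (0.00423 to 0.404 over the alternatives, past the threshold in 4 of 29, the 6-library fit included). In those libraries the spermatogonial stem cell genes went both ways: Zbtb16 fell by 1.42 (SE 0.318, adjusted p = 0.0281) and Id4 rose by 0.48 (SE 0.102, adjusted p = 0.0243), with alternatives up to 0.407 and 0.404. Undifferentiated spermatogonia (6 members, medians -0.00833 to 0.124 over the 3 comparisons, lowest adjusted p = 0.831), differentiating spermatogonia (9, -0.26 to 0.38, 0.438), meiotic prophase (14, -0.27 to 0.32, 0.141) and pachytene and later spermatocytes (9, -0.24 to 0.52, 0.0819) were not called in any comparison. Elongating spermatid genes in BdE minus BP had a median of 2.21 (adjusted p = 0.105).

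Sox9, a gene of Sertoli cells, which nurse the germ cells, stood at 174 ± 18.4 CPM in BP, 165 ± 6.71 in BE and 168 ± 12.5 in BdE (SD, n = 3). Their list was not called (18 members, medians 0.0468 to 0.29 over the 3 comparisons, lowest adjusted p = 0.161). In the 6 BP and BdE libraries 6 members rose and 1 fell over all genes tested, and 6 and 1 adjusted over the list alone. Among those that rose were Aard (0.59, SE 0.083) and Rhox8 (0.66, SE 0.105). Endothelial genes had medians from -0.51 to -0.24 (9 members, lowest adjusted p = 0.105), and Vwf, the von Willebrand factor gene, fell by 0.56 (SE 0.109) in those libraries. Cell cycle genes had medians from -0.30 to -0.14 (16 members, lowest adjusted p = 0.0823), with the replication gene Mcm6 at -0.73 (SE 0.108) in the 6 libraries. Cyp11a1, the enzyme gene for the entry step of steroid synthesis, stood at 976 ± 105 CPM in BP, 639 ± 542 in BE and 396 ± 245 in BdE and did not pass (adjusted p = 0.07 in the 6 libraries by edgeR).

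The other lists were not called in any comparison with all 9 libraries by camera. Members, the range of the medians over the 3 comparisons and the lowest adjusted p are given for each. They were p53 targets (11, -0.13 to 0.16, 0.0823), oxidative phosphorylation of nuclear genes (19, -0.0479 to 0.00941, 0.274) and erythroid cells (6, -0.0112 to 0.28, 0.311). Next were immediate early genes (10, 0.0391 to 0.15, 0.311), inflammatory cytokines and Toll-like receptors (11, -0.19 to -0.0629, 0.358) and spermatogonial niche factors (11, -0.15 to 0.0552, 0.369). Then came blood-testis barrier junctions (15, -0.0714 to 0.00591, 0.407), retinoic acid signalling (10, -0.19 to 0.0866, 0.407) and antioxidant defence (17, -0.15 to -0.0125, 0.407). The last were cytosolic ribosomal proteins (19, -0.00868 to 0.0412, 0.51), adipocytes (8, -0.0152 to 1.08, 0.588), extracellular vesicle machinery (14, -0.0149 to 0.026, 0.608) and apoptosis machinery (14, -0.0465 to 0.0151, 0.846). The adipocyte median in BdE minus BE was 1.04 and turned to -0.98 without BdE 7. The remaining 4 lists had too few tested members for a list test. Round spermatid genes had 3 tested members, of which the acrosome gene Spaca1 rose in the 6 BP and BdE libraries (0.66, SE 0.154, edgeR adjusted p = 0.0322; 301 to 843 counts per library; up to 0.404 over the alternatives). Lymphocyte genes had 2, of which Cd4 fell there (-1.01, SE 0.204, adjusted p = 0.0216; up to 0.406). Photoreceptor genes, a check on the tissue, had 3 tested members: Prph2 had 1651 to 2865 counts per library, and the photoreceptor regulator Crx had 0 in every library. Of the 12 epididymal genes 0 were tested.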

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

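Tests chosen only after the results were seen were the length and GC correction, the tests of a swap, of the counts of the mitochondrially encoded genes and of Leydig cell number, and the splits of the 6-library fit; the other fits and splits were planned.

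Prrc2b, which codes for a protein of RNA granules, stood out because the 2 exosome groups differed in it: -1.94 on the log2 scale in BdE minus BE, while BP lay between them. The 6 libraries make 10 splits, too few for a share under 0.05: the real split gave 1 gene and the highest other split 6, and 9 of the 10 splits gave at least 1. A count of 1 gene therefore does not set the real groups apart from mixed ones. Prrc2b overlaps Gm13610 on the other strand, which had at most 27 counts in any library, so reads of that gene are too few to account for the fall.

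Library BE 6 lay with the BP libraries in the mitochondrial share, in the first principal component and in the Leydig, cholesterol and macrophage genes. A swap with a BP library needs a BP library out of place: on genes chosen without it, the median position of a left-out BP library between the other BP libraries (0) and BdE (1) was at most 0.102, which argues against a swap. A shared trend on transcript length and GC content as the whole cause is argued against as well, since after its removal the lowest correlation of BE 6 with a BP library still exceeded the highest with BE 7 or BE 8 by 0.0199 (0.0256 before). As a part of the cause that trend stays open, and so does library quality beyond it, untested. That BE 6 may be a BP library under a wrong label stays open: it lay past the middle of the way to BdE on 10.6% of the chosen genes, within the 10.5 to 15.4% of left-out BP libraries. A weak response of that sample to the exosomes stays open too, untested. Ccdc71 and Abl1 in BE 6 lay at the level of the other BE libraries (65.8 and 171 CPM), unlike in BP. Both genes were picked by a threshold that BE 6 helped to set, so they cannot tell whether BE 6 responded.

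Cholesterol, fatty acid, macrophage, fibroblast, myoid and Leydig genes were lower and mitochondrially encoded genes higher in BdE than in BP with the preset correlation of camera, and 0 of these lists passed with an estimated one (adjusted p = 0.776). Counts taken up by the mitochondrially encoded genes can change all other genes by no more than -0.102 on the log2 scale. TMM normalization already takes out a fall common to all genes (median of all genes 0.0137). List medians set against that value therefore cannot decide this explanation. Of the 6 list medians 5 lay below it by more than 2 SE (fatty acids did not). That SE is of the median over list members taken as independent, so it is too small for genes that move together. The list calls cannot decide whether a trend on gene length and GC content is the whole cause. After its removal 7 of the 7 lists passed, but with the preset correlation, under which mixed splits gave as many lists. The medians of the 6 lower lists then ran from -0.658 (Leydig) to -0.302 (fatty acids), so they kept their direction. Whether these remaining falls exceed those of mixed groups was not tested. As the whole or a part of the cause that trend stays open, and so does library quality beyond it. The mitochondrial median went from 0.78 to 0.35 with the correction. The rank correlation with transcript length of expression relative to the mean of the libraries also separated the libraries. It was 0.21 to 0.286 in BP and 0.258 in BE 6, against -0.26 to -0.0907 in the other 5 libraries. If no other cells express the Leydig genes, fewer Leydig cells alone would lower them all alike. The 12 members moved apart instead (Cochran's Q 129 on 11 degrees of freedom, from the SEs of edgeR), with Star at -1.10 (SE 0.219) and Insl3, a Leydig cell hormone gene, at 0.312 (SE 0.0991). Q takes the members as independent, and other cells may express some of them. Fewer Leydig cells as a part of the cause therefore stay open. An earlier criterion, changed after the values were seen, asked for 2 members higher by more than 2 SE and only Insl3 was. An effect of the BdE exosomes on steroid and lipid genes of Leydig cells is a candidate explanation. It was not tested apart from loss of Leydig cells or of the other cell types. Of the 10 splits of the 6 libraries 8 gave at least as many lists in the 6-library fit (7 real, 11 the highest other). The number of lists therefore does not set the real groups apart from mixed ones.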

How the results depend on the processing

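Alternatives chosen only after the results were seen were limma on log2(FPKM+1), robust edgeR, the fit without mitochondrially encoded genes, the length and GC correction, the fit without BE 6 and BP 5, the 6 libraries with each left out, and KEGG; the other tests were planned. The lists past the threshold in BE minus BP and BdE minus BP kept their direction in all 30 or 31 alternatives of each, and their number stayed within 1.5 times the main count except as given here. Of 12687 values of named genes under alternatives 11288 kept direction and side of the threshold, 943 came to pass, 32 no longer passed, 424 that did not pass changed sign and 0 reversed; of 2670 list values these were 2262, 84, 57, 255 and 12. The cause of the changes below was not tested unless stated.

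Counts of genes are given in the order BE minus BP (main 2), BdE minus BP (1), BdE minus BE (1), the 3 groups (2), the overlap of both responses (1) and lists in BdE minus BE (0), as far as they moved. Limma on log2(FPKM+1), pseudocounts of 0.1 and 0.5, and trend with robust each gave 1 and 2 genes against BP. The correlation of the 2 responses, 0.777 from the fitted fold changes (0.779 from group means of log2 CPM), moved to 0.581 with no filter and 0.664 with the replicate term. No filter gave 3 in BdE minus BP, 2 in BdE minus BE and 6 lists. A mean FPKM of 5 or more gave 0 in BdE minus BE, 1 among the groups and 1 list. Quantile normalization took the mitochondrial median to 0.0966 (BE minus BP) and 0.0257 (BdE minus BP), neither past the threshold. TPM gave 0, 0 and, among the groups and in the overlap, 1 and 0. Only the 6 libraries compared gave 0, 3078, 0 and an overlap of 0, where the spread comes from fewer samples. Limma without trend gave 2 in BdE minus BP and 2 in BdE minus BE. Array weights, which gave BE 6 a weight of 0.126 and BE 8 4.32, gave 7056, 5479, 29, 6757, 4700 and 2 lists, and the cholesterol median in BdE minus BE turned from -0.16 to 0.252. The replicate term, although no label says that the numbers pair the libraries, gave 0 of each count of genes and 8 lists. The meiotic covariate gave 1 in BE minus BP, 0 in BdE minus BE and 1 among the groups. DESeq2 gave 61, 389, 26, 194, 28 and 2 lists, and its size factors in edgeR 1 list. Without the mitochondrially encoded genes there was 1 list. The length and GC correction gave 2 in BdE minus BP, 0 in BdE minus BE, an overlap of 2 and 4 lists. Without BE 6 and BP 5 the counts were 3064, 1781, 6, 1847, 1646 and 7 lists, and the medians in BdE minus BE turned to 0.19 (Leydig), 0.355 (fibroblasts), 0.321 (macrophages), 0.487 (cholesterol) and -0.244 (mitochondrial). An unadjusted p under 0.05 with a 2-fold change gave 270, 535, 78 and an overlap of 138. Camera with an estimated correlation and fry gave 0 lists in BE minus BP and 0 in BdE minus BP.

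The correlation of the 2 responses ran from 0.596 (without BE 7) to 0.819 (without BP 6). Leaving out each library in turn gave 0 (without BP 6) to 4351 genes (without BE 6) in BE minus BP, 0 to 3257 in BdE minus BP, 0 to 6 (without BdE 5) in BdE minus BE, 0 to 3509 among the groups and 0 to 2869 in the overlap. Lists in BdE minus BE went from 0 to 8 (without BE 8 or BdE 6), and lists differing in level among the groups from 0 to 8 (without BE 6). In BdE minus BE the medians ran from -0.366 to 0.19 for Leydig genes, -0.257 to 0.355 for fibroblasts, -0.238 to 0.321 for macrophages, -0.518 to 0.487 for cholesterol, -0.244 to 0.209 for mitochondrially encoded genes and -0.985 (without BdE 7) to 1.59 for adipocytes. In the 6 BP and BdE libraries the count ran from 743 (without BP 6) to 3140 (without BdE 6), against 3078.

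Depth limits low genes: with 57923652 counts or more per library, 3 counts are at most 0.0518 CPM. The spread between libraries limits the rest, since simulated 2-fold changes were recovered in 38 to 50% of genes. The simulation drew genes independently, without the shift of BE 6 as a whole library, so recovery in these data may be lower. Chml, 34.7-fold lower in BdE minus BP with all 9 libraries, did not pass (edgeR adjusted p = 0.0703).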

Other observations

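Tests chosen only after the results were seen were the KEGG pathways, the splits of the 6-library fit and the test of epididymal transcripts; the criterion for each count of splits was written before that count was seen, and the other splits were planned.

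KEGG pathways, which hold more genes than the lists, showed pathways of cell adhesion lower and the Ribosome and Oxidative phosphorylation pathways higher against BP with the preset correlation. The trend on gene length separated the same libraries (rank correlation 0.21 to 0.286 in BP and -0.26 to -0.0907 in BE 7, BE 8 and BdE). With an estimated correlation 0 of 296 pathways passed in any comparison (lowest adjusted p = 0.494 in BE minus BP, 0.444 in BdE minus BP and 0.953 in BdE minus BE). In BdE minus BP, Focal adhesion had a median of -0.23 (camera adjusted p = 0.000169), ECM-receptor interaction -0.56 (adjusted p = 0.000175), Ribosome 0.23 (adjusted p = 0.000169) and Oxidative phosphorylation 0.24 (adjusted p = 0.000304). In BE minus BP they had -0.24 (0.00125), -0.37 (0.00212), 0.14 and 0.15 (0.0022 each), and Steroid biosynthesis had -0.49 (0.0022). The fixed list of 19 cytosolic ribosomal proteins was not called (medians 0.0412 in BdE minus BP and -0.00868 in BE minus BP, adjusted p = 0.655 and 0.846), while the Ribosome pathway holds 131 tested genes. The list of nuclear oxidative phosphorylation genes was not called either. The KEGG pathway holds 121 tested genes, mitochondrially encoded genes among them. Its nuclear members were not tested apart, so why it differs from the list is not known. With the preset correlation 81 pathways passed in BE minus BP (78 lower), 118 in BdE minus BP (113 lower) and 1 in BdE minus BE (Lysosome, median -0.0957, adjusted p = 0.012). After the length and GC correction 25 and 32 passed against BP, so most calls did not stand without that trend. Whether the pathways named here were among the 25 and 32 was not examined. With a mean FPKM of 5 or more 23 and 62 passed. No filter gave 122 in BE minus BP and 0 in BdE minus BE. In BdE minus BE there were 0 with the meiotic covariate, 4 with the replicate term and 16 without BE 6 and BP 5. There were 17 without BE 6, 32 without BE 7, and 2 without BdE 5 or BdE 6.

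The 6 libraries of a pair of groups make 10 splits, too few for a share under 0.05, so only the real count and the highest other are given. In BE minus BP these were 2 and 2 genes (2 splits with as many), 8 and 11 lists (3 splits) and 81 and 114 pathways (3 splits). In BdE minus BP they were 1 and 0 genes (1 split), 8 and 10 lists (7 splits) and 118 and 32 pathways (1 split), and in the 6 libraries alone 3078 and 2 genes (1 split). In BdE minus BE they were 0 and 16 lists (10 splits) and 1 and 56 pathways (10 splits). In each comparison another split gave more lists than the real one, so the number of lists does not set the real groups apart. For the 3 groups, 34 of 100 splits drawn from 280 gave at least the real 2 genes, so chance is not excluded; the highest other gave 19, with BP 6, BP 7 and BE 6 as a group and BE 7, BdE 5 and BdE 7 as another, which points to a structure of the samples. For the overlap, 25 of 100 splits drawn from 840 gave at least 1 gene (highest other 3), so chance is not excluded.

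Epididymal transcripts appeared in library BP 5. Crisp1, a sperm-coating protein gene of the epididymis, had 38837 counts there, Adam7, a surface protease gene, 7920 and Rnase9 1651, while Crisp1 and Adam7 had 197 and 21 counts in BdE 7. Some epididymal tissue in BP 5 may be their source. RNA from all parts of the epididymal epithelium is argued against, since 5 of the 5 lipocalin genes on the preset list, abundant in the epididymis, had 0 counts in BP 5. An earlier criterion, changed after the values were seen, counted preset genes highest in BP 5, which were 3 of 12. A part of the epididymis that lacks lipocalin transcripts was not tested.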
